A study of Gallus gallus with 24 samples.

How the data were processed

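The series measured RNA of spleen and cecum from chickens of 3 lines, Leghorn (G-B1 in the labels), Fayoumi and broiler, on spotted 2-colour arrays. Each array held RNA of 3 birds given SE, an abbreviation the labels do not expand, in the first channel and RNA of 3 birds without challenge in the second. The birds were challenged at day 1 and tissue was taken 2 h or 16 h later. The labels give 24 arrays, 2 for each of the 12 groups of line, tissue and time, of which 1 array per group is titled as a replicate. They do not say whether that replicate array held the same RNA pools as the first, other birds, or the same pools with the dyes exchanged. P-values therefore measure only the spread between arrays, which can be technical.

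The values are the table deposited for the 24 arrays, with 15769 rows of probe identifiers. The authors deposited 1 value per probe and array, read here as a log2 ratio of the 2 channels, since the values lie on both sides of 0. The scanner, image software, background correction and normalization are not given in the sources used here, and the log base and the direction of the ratio are not given either. Array medians of the deposited log2 ratios ran from -2.05 to 1.27, so the columns had not been brought to a common centre. The base of 2 was inferred, and the column of the broiler cecum 16 h replicate array bears on it: it held the value 1 in 9194 cells, 1.585 in 614 cells and 1 other value, with 5960 cells (37.8%) blank. These are the base-2 logarithms of 2 and 3. A column with so few different values is not a table of ratios, and it was left out. Broiler cecum at 16 h was thus represented by 1 array, and 23 arrays were used.

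The dyes are not named in the labels. Arrays of 1 group correlated at less than -0.3 in 5 of the 11 groups with a pair, so the direction of the ratios was not settled. Signs are given as deposited, as positive or negative log2 ratios, and no sentence reads a positive value as higher RNA in challenged birds. The comparisons were repeated with the sign of every array titled as a replicate turned.

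Each array was centred on the median of the tested probes. The 160 control spots were left out of the tests: 32 spots for each of 4 names of plant genes (Cab, NAC1, PRKase and RUBISCO) and 32 spots named for chicken genomic DNA. The file does not say what RNA, if any, was added for the plant spots. A probe was tested with a value on at least 20 arrays, which left 15609 probes, all with a value on all 23 arrays. The model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 23 arrays with a mean for each of the 12 groups, which left 11 residual degrees of freedom. Contrasts were each group mean against 0, the mean of the 3 lines against 0 for each tissue and time, differences between times and between tissues, and an F-test of the 3 lines. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05, and all tests were two-sided. Unadjusted p-values under 0.05 are expected by chance for 780 of the probes. Depth is not a property of these values, and the number of arrays limited the precision: the 95% interval of a probe's group mean had a median half-width of 0.88 on the log2 scale with 2 arrays and 1.24 with 1 array.

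The model was tested on simulated data for the mean response of spleen at 2 h, over 15609 probes. Of 100 probes given a log2 change of 1 on all 6 arrays, 53% were recovered, and of 100 given a change of 2, 94%, with 6 false calls. The simulated noise was independent between probes and arrays, so it left out the deviations that spleen arrays of a round shared. With the same changes added to the real spleen arrays, after the signs of 3 of them were turned, 60% and 100% were recovered with 2 false calls. The 3 were 1 array of each line, so pairs that opposed each other as deposited then ran the same way. That lowered the spread between the arrays of a group. These 2 recoveries therefore do not describe the fit with the signs as deposited.

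The file does not pair probes with genes. None of the identifiers was found among the gene identifiers, symbols, synonyms and accessions of the reference gene table (0 of 15769). The 22 gene lists and the 4 gene list results fixed before the data were examined could therefore not be read, and the rule for named genes, which takes only probes with 1 gene symbol, named none. That rule took, for each tissue and time, up to 12 genes per direction past the threshold with 1 sign on all arrays, and for each single line the 3 genes with the largest mean past the threshold with 1 sign on both arrays. In its place, the 2 probes with the largest positive mean and the 1 probe with a negative mean among those past the threshold in Fayoumi cecum at 16 h are given by identifier. PEN_c-rel is given as well, chosen after the file was opened because its identifier contains a gene name, and the other 2 probes named PEN, PEN_mtd and PEN_TF-10, after their values were seen. Their exact p-values were adjusted over 12 tests, 3 probes in 4 combinations of tissue and time. Probes were also grouped by the first part of their identifier: C00041 with 11447 probes, Pat with 1983, DT40subNB with 1798 and DKFZ426 with 378. These groups, their Fisher's exact tests and exact sign-flip tests over arrays were likewise chosen after the file was opened.

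Alternatives fixed before the data were examined were the values as deposited, scaling of the arrays to a common median absolute deviation (limma's normalizeMedianAbsValues, which is what its scale method applies to log ratios), other filters on missing values, a fit for each tissue, array weights, replicate arrays averaged, a replicate block, the slide number range as a random block, turned signs, and leaving out each array. In spleen, the deviations of an array from its group mean were shared between lines within a round, that is, among first arrays or among replicate arrays. Over the 3 pairs of lines they correlated at 0.73 to 0.78 at 2 h and at 0.37 to 0.71 at 16 h, so the rounds pair the spleen arrays at each time, by the data and not by the labels. Between the 2 times the deviations of a round ran opposite ways, with a mean correlation of -0.64, which the planned block within each tissue does not model. In cecum the correlations were -0.05 to 0.20 at 2 h and 0.25 for the 1 pair at 16 h. A replicate block within each tissue and time was therefore added, which leaves the group means as they are, changes only the spread, and leaves 7 residual degrees of freedom. The single broiler cecum array at 16 h stayed outside the block. Also chosen after seeing the data were the plant spot median of each array as a covariate, the removal of a trend shared by the spleen arrays at 2 h (a lowess curve with a span of 0.3 on the difference between the arrays of a group, averaged over lines), and a fit without the 3 arrays whose median absolute deviation was above 0.9. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene set tests were not run, since no probe could be placed in a set.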

Results

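Ratios between challenged and unchallenged RNA pools were measured in spleen and cecum of Leghorn, Fayoumi and broiler chicks, 2 h and 16 h after challenge with SE. The comparisons asked which probes departed from 0 in each tissue and time, and whether the 3 lines, the 2 times and the 2 tissues differed. The 12 groups had 2 arrays each, except broiler cecum at 16 h with 1 array in use, and 15609 probes were tested. Signs are those of the deposited ratios, whose direction was not settled. Probes carry clone names, so the results are given for probes and for the 4 clone groups C00041, Pat, DT40subNB and DKFZ426. DT40 is also the name of a chicken B cell line, and the file does not state where the DT40subNB clones came from.

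In the cecum of Fayoumi chicks at 16 h, 500 probes departed from 0 in limma's test at an adjusted p below 0.05. Of these, 499 had positive and 1 had negative ratios, and all 500 had the same sign on both arrays. The median log2 ratio of the 499 positive probes was 1.97, and their means ran from 1.09 to 4.09. The largest was DT40subNB_1A7 at 4.09 ± 0.76 (SD, n = 2; limma adjusted p = 0.00718), with 4.63 and 3.55 on the 2 arrays. DT40subNB_1F5 followed at 3.93 ± 0.55 (SD, n = 2; limma adjusted p = 0.00718). The negative probe was C0004105_G5 at -1.34 ± 0.66 (SD, n = 2; limma adjusted p = 0.0472). Its call was lost with each tissue fitted alone (limma adjusted p = 0.0748), with the replicate block within each tissue (0.0676), as deposited (0.977), with the sign of the replicate array turned, and in 18 of the 23 fits without 1 array. It was kept with the replicate block within each tissue and time (limma adjusted p = 0.00928).

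DT40subNB clones made up 185 of the 499 positive probes, which is 10.3% of the 1798 DT40subNB clones tested. The share was 1.91% of the C00041 clones (219 of 11447), 3.83% of the Pat clones (76 of 1983) and 5.03% of the DKFZ426 clones (19 of 378). Against all other tested probes, the odds ratio was 4.93 for DT40subNB (Fisher's exact test, two-sided, p = 8.04e-52, adjusted p = 6.43e-51 over 8 tests) and 0.270 for C00041 (exact p = 3.23e-45, adjusted p = 1.29e-44). The Pat and DKFZ426 clones did not pass (adjusted exact p = 0.117 and 0.0835). With the trend of the spleen arrays removed, DKFZ426 clones did pass (21 clones, odds ratio 2.02, Fisher's exact test, adjusted p = 0.00716) and Pat clones did not. Probes on 1 array are not independent replicates, so these tests describe the 2 arrays. The group of DT40subNB clones had a median log2 ratio of 0.47 in this group, averaged over both arrays, with 0.26 on the first and 0.69 on the replicate array. It was 0.40 with the arrays scaled to a common spread and 0.23 as deposited, -0.21 with the sign of the replicate array turned, and 0.04 with the trend of the spleen arrays removed, a setting chosen after seeing the data.

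These calls rested on both Fayoumi arrays. Without either one, 0 of the 15609 probes passed in limma's test, against 2417 at an unadjusted p below 0.05 with both. With the sign of the replicate array turned 0 passed, and with the values as deposited, whose medians were -1.04 and 0.56 on these arrays, 2 passed, both DT40subNB clones. Without an array of another cecum group the count ran from 293 (without either Fayoumi 2 h array) and 313 (without either broiler 2 h array) to 1078 (without either Leghorn 16 h array), and without either Leghorn spleen 2 h array it was 793. Of the planned settings, the replicate block within each tissue gave 312, all positive, scaled arrays 864 and array weights 1939. With the replicate block within each tissue and time, chosen after seeing the data, 2378 passed (2366 positive, 12 negative). With the trend of the spleen arrays removed, 552 passed, of which 100 were negative.

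In the spleen of Leghorn chicks at 2 h, 41 probes passed in limma's test, 39 with positive and 2 with negative ratios, all with the same sign on both arrays. The median log2 ratio of the 39 was 2.48, from 1.66 to 4.76. Pat clones made up 15 of the 39, or 0.756% of the 1983 Pat clones, with an odds ratio of 4.32 against all other probes (Fisher's exact test, two-sided, p = 4.32e-05, adjusted p = 0.000115 over the same 8 tests). The 15 Pat clones became 2 with the sign of the replicate arrays turned, 5 without the replicate array, 3 with each tissue fitted alone and 0 with scaled arrays or array weights. Without the first array, Pat clones were 14 of 550 positive probes and the odds ratio was 0.17, the opposite direction, and without the replicate array they were 5 of 8 (odds ratio 11.5). C00041 clones made up 21, with an odds ratio of 0.423 (exact p = 0.00994, adjusted p = 0.0199), and without the first array their odds ratio was 4.22. DT40subNB clones made up 2, with an adjusted exact p of 0.357. With the trend of the spleen arrays removed, a setting chosen after seeing the data, their odds ratio was 0.341 (Fisher's exact test, adjusted p = 0.0165). Over all probes the 2 arrays of this group correlated at -0.40. The count was 688 without the first array and 8 without the replicate array, and it was 20 or 21 without either Fayoumi or broiler spleen array at 16 h or either Fayoumi cecum array at 2 h. It was 31 with the planned replicate block within each tissue, 6 with each tissue fitted alone, 0 with scaled arrays or array weights, and 1795 (31 positive, 1764 negative) with the sign of the replicate array turned. The replicate block within each tissue and time gave 555 (413 positive, 142 negative).

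In the cecum of Leghorn chicks at 16 h, 3 probes passed, all with positive ratios; as deposited 3 passed, 1 positive and 2 negative. This count was 699 without the first array and 0 without the replicate array or with the replicate array's sign turned, and it lay between 0 and 6 without single arrays of other groups. It was also 0 with the planned replicate block within each tissue, with scaled arrays, with array weights and with each tissue fitted alone. It was 349 with the replicate block within each tissue and time, chosen after seeing the data (325 positive, 24 negative). No probe passed in the other 9 groups. In limma's test the numbers at an unadjusted p below 0.05 were 104 for Fayoumi and 352 for broiler spleen at 2 h, against 780 expected by chance. They were 549, 28 and 63 for Leghorn, Fayoumi and broiler spleen at 16 h. In the cecum they were 677, 347 and 462 for Leghorn, Fayoumi and broiler at 2 h, and 299 for the single broiler array at 16 h. Broiler spleen at 2 h had 36 probes past the threshold without the first array, and 504 (25 positive, 479 negative) with the sign of the replicate array turned. Leghorn spleen at 16 h had 14 probes and the broiler cecum array at 16 h had 25 with the replicate block within each tissue and time.

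Averaged over the 3 lines, 0 probes departed from 0 in limma's test in any tissue and time. The smallest adjusted p was 0.173 for spleen at 2 h, 0.105 for spleen at 16 h, 0.342 for cecum at 2 h and 0.108 for cecum at 16 h. At an unadjusted p below 0.05 the counts were 695, 169, 306 and 1375 in the same order. Ratios were positive on all 6 spleen arrays at 2 h for 124 probes and negative on all 6 for 129, where independent signs would give 244 each (1.56% of probes). In spleen at 16 h the counts were 147 and 181, and in cecum at 2 h 204 and 202. In cecum at 16 h, 528 probes were positive and 400 negative on all 5 arrays, where independent signs would give 488 each. With the trend of the spleen arrays removed, a setting chosen after seeing the data, the positive and negative counts were 254 and 285 in spleen at 2 h, 365 and 322 in spleen at 16 h, 287 and 233 in cecum at 2 h and 521 and 545 in cecum at 16 h. The cecum response at 16 h was the one that moved furthest with single arrays. Without the broiler array, which was the only array of its group, the mean covered Leghorn and Fayoumi alone, and 475 probes passed. With replicate arrays averaged 130 passed, all positive, but 1 with the planned replicate block within each tissue. With the sign of the replicate arrays turned, 3769 probes passed in spleen at 2 h (415 positive, 3354 negative) and 0 in the other responses. With the replicate block within each tissue and time, 223 passed in spleen at 2 h (204 positive, 19 negative), 4 in spleen at 16 h, 0 in cecum at 2 h and 880 in cecum at 16 h (858 positive, 22 negative).

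As whole groups, and with the signs as deposited, no clones departed from 0 beyond the spread between arrays. The median of the Pat clones in cecum at 16 h averaged 0.29 ± 0.45 (SD, n = 5), positive on 4 of 5 arrays, with an exact sign-flip p of 0.3125 and an adjusted p of 0.625 over 16 tests. The smallest p of the 16 was 0.1875, for the DKFZ426 clones in cecum at 16 h (0.24 ± 0.34, SD, n = 5, positive on 4 of 5 arrays, exact test, adjusted p = 0.625). Turning the replicate arrays changed the Pat and DKFZ426 medians to -0.33 and -0.23. As deposited they were 0.060 and 0.0076, and with the trend of the spleen arrays removed -0.0036 and 0.011. Without the Fayoumi replicate array they were 0.15 and 0.13, and without the first Leghorn array 0.40 and 0.34. With 5 arrays the exact test cannot go below 0.0625, and with 6 arrays not below 0.03125. In spleen the result depended on the sign. With the replicate arrays turned, the Pat medians of Leghorn, Fayoumi and broiler were 0.40, 0.35 and 0.40 at 2 h. At 16 h they were -0.14, -0.29 and -0.31. The C00041 medians had the opposite sign in each of these groups. C00041 holds 73.3% of the probes, so centring on the array median by itself sets its median opposite to that of the remaining probes. The exact tests were not run on turned ratios.

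PEN_c-rel, a probe whose identifier contains the name of an NF-kB family gene, was negative on 5 of 5 cecum arrays at 16 h. Whether the spot holds that gene is not given in the sources used here. Its mean over the lines was -0.40 (SE 0.23, SD between arrays 0.19, n = 5), with a limma adjusted p of 0.721 and an exact sign-flip p of 0.0625, the smallest that 5 arrays allow. With the sign of the replicate arrays turned the mean was -0.05. In cecum at 2 h the mean was 0.36 ± 0.42 (SD, n = 6), positive on 5 of 6 arrays (exact p = 0.09375), and -0.13 with the replicate arrays turned. In spleen it was -0.09 ± 0.58 (SD, n = 6) at 2 h and 0.12 ± 0.62 (SD, n = 6) at 16 h, and both signs were opposite in the values as deposited (0.53 and -0.05). None of the 4 passed the correction. Of the other 2 probes named PEN, chosen after their values were seen, PEN_mtd was negative on 6 of 6 cecum arrays at 2 h. Its mean was -0.51 ± 0.37 (SD, n = 6; limma adjusted p = 1.00; exact p = 0.03125, adjusted p = 0.25 over the 12 tests of the 3 PEN probes), and -0.03 with the replicate arrays turned. PEN_TF-10 did not pass in any of the 4 (smallest exact p = 0.0625, adjusted p = 0.25).

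**Figure D1:**
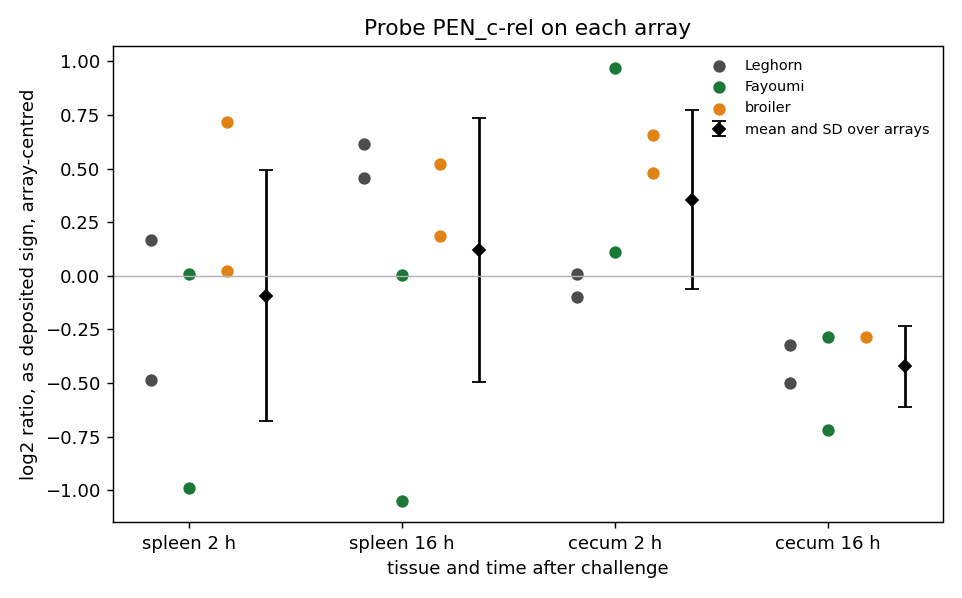
Log2 ratio of probe PEN_c-rel on each array (points, coloured by line; vertical axis, array-centred log2 ratio with the deposited sign) for the 4 combinations of tissue and time (horizontal axis), with the mean and SD over arrays as diamonds with bars. All 5 cecum arrays at 16 h lie below 0, and the arrays of the other combinations lie on both sides of it.

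In the planned fit no probe passed limma's F-test for a difference between the 3 lines. The count was 0 in spleen at 2 h, spleen at 16 h, cecum at 2 h and cecum at 16 h. At an unadjusted p below 0.05 the counts were 332, 109, 490 and 1044, against 780 expected by chance. The deviations that spleen arrays of a round shared stayed in the spread of this fit, so a count of 0 does not show that the lines were alike. The count for cecum at 16 h was 45 without the Leghorn replicate array, and that for spleen at 2 h was 10 without the broiler replicate array. Under settings chosen after seeing the data, the count for cecum at 16 h was 463 with the plant spots as a covariate, 85 with the trend of the spleen arrays removed and 581 without the 3 widest arrays. With the replicate block within each tissue and time it was 548, and that for spleen at 2 h was 28. The 500 probes of Fayoumi cecum at 16 h are therefore not shown to differ from the other lines by the planned test. Across probes, which are not independent replicates, the mean ratios of cecum at 2 h correlated at 0.54 between Fayoumi and broiler, at -0.37 between Leghorn and Fayoumi and at -0.39 between Leghorn and broiler. With the replicate arrays turned these became 0.07, 0.20 and -0.05. Without the Leghorn replicate array the correlations of Leghorn were -0.08 with Fayoumi and -0.05 with broiler.

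Between 2 h and 16 h, 0 probes differed in spleen and 0 in cecum in limma's test (452 and 978 at an unadjusted p below 0.05). Between cecum and spleen, 0 differed at 2 h and 0 at 16 h (284 and 470 unadjusted). The slide numbers of the 2 tissues did not overlap, so tissue and slide number range cannot be told apart in these counts. The median half-width of the 95% interval was 0.72 in spleen and 0.77 in cecum for the differences between times. For the differences between tissues it was 0.72 at 2 h and 0.77 at 16 h. These intervals are not adjusted for the number of probes. A typical probe would thus need a larger change than this to pass the threshold. With the replicate arrays turned, 4757 probes differed between times in spleen and 1832 between tissues at 2 h. Without the first Leghorn cecum array at 16 h, 16 probes differed between times in cecum and 22 between tissues at 16 h. Under the replicate block within each tissue and time, 261 differed between times in cecum (253 positive, 8 negative) and 0 in the other 3 comparisons.

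Arrays of 1 group often opposed each other: of the 11 pairs, 6 correlated below 0 and 5 below -0.3. Over all probes the pairs correlated at -0.40, -0.51 and -0.59 in Leghorn, Fayoumi and broiler spleen at 2 h, and at 0.08, -0.65 and -0.14 in the same lines at 16 h. In cecum they correlated at 0.09, 0.28 and 0.29 at 2 h, and at -0.31 in Leghorn and 0.54 in Fayoumi at 16 h. Among the 253 pairs of arrays, 74 correlated below -0.3 and 62 above 0.3.

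**Figure D2:**
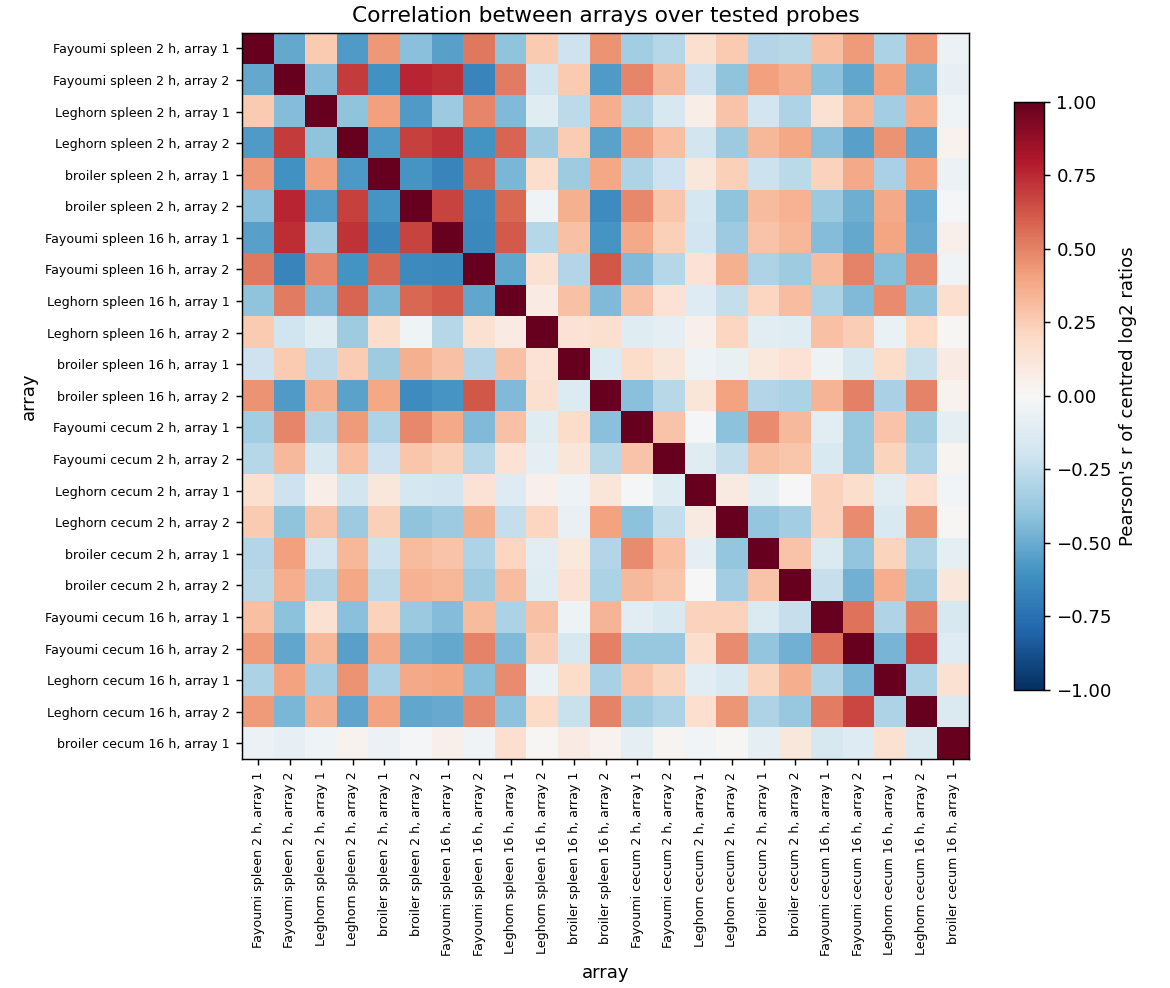
Pearson correlation of array-centred log2 ratios over the 15609 tested probes for each pair of the 23 arrays (both axes list the arrays by tissue, time and line; colour gives r from -1 to 1). The spleen pairs of 1 group at 2 h are blue, at -0.40, -0.51 and -0.59, and the Fayoumi cecum pair at 16 h is red, at 0.54.

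The first principal component of the probes held 45.9% of their sum of squares, and the loadings of the arrays on it followed the control spots with plant gene names. Over 23 arrays, the median of the plant spots correlated with the loading at Pearson's r = 0.94 and Spearman's rho = 0.92 (permutation p = 1e-05 for each, the smallest the permutations could give; adjusted p = 2e-05, 3 relations). Without the 2 arrays farthest from the median r was 0.90. Within tissues, r was 0.97 over 12 spleen arrays (rho = 0.94, permutation p = 1e-05 and 4e-05) and 0.91 over 11 cecum arrays (rho = 0.90, permutation p = 0.00011 and 0.00044), with adjusted p-values of 2e-05 and 6e-05 in spleen and 0.00013 and 0.00044 in cecum. Left without their 2 farthest arrays, r was 0.92 in spleen and 0.86 in cecum.

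**Figure D3:**
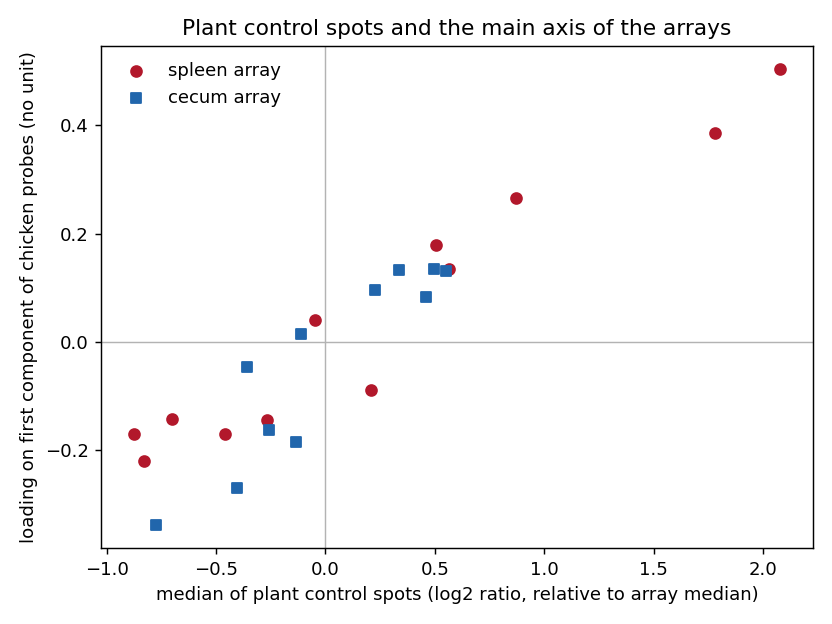
Loading of each array on the first principal component of the tested probes (vertical axis, no unit) against the median of its 128 plant control spots (horizontal axis, log2 ratio relative to the array median), for spleen arrays (circles) and cecum arrays (squares). The arrays rise from the lower left to the upper right, with r = 0.94 over 23 arrays.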

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

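The tests of the opposed spleen arrays and of the positive probes of Fayoumi cecum at 16 h were chosen after those results had been seen. So were the 2 corrections for a possible array bias and the replicate block within each tissue and time.

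The control spots with plant gene names, which entered no comparison, had ratios away from the array median. On 9 of 23 arrays their median lay farther from 0 than the array's own median absolute deviation. These are ratios, so they do not show whether the spots held signal over background. In spleen at 2 h the plant medians of the first and the replicate array were -0.88 and 2.08 in Leghorn, -0.27 and 0.87 in Fayoumi, and -0.70 and 1.78 in broiler. Relative to the array median, all 12 combinations of plant gene and line had opposite signs on the 2 arrays. As deposited, they opposed in Leghorn only. In Fayoumi and broiler the deposited medians of the first arrays were 0.48 and 1.27, with lowest plant genes at -0.41 and -0.89 relative to them. On the replicate arrays they were -0.27 and 1.16, with lowest plant genes at 0.74 and 1.31. Every plant gene of these 2 lines was thus positive on both arrays as deposited.

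The arrays of 1 spleen group opposed each other, with correlations down to -0.65, except in Leghorn at 16 h (0.08). A chicken response that ran opposite ways on the 2 arrays would leave spots of plant genes alike, provided that no plant RNA was added unequally, which the labels do not state. The plant medians are relative to the median of the tested probes, so the response must also not have moved that median. Under both conditions the tables argue against such a response at 2 h, where the plant medians of a group differed by at least 1.14. The second condition was not tested. In Fayoumi, with the difference of 1.14, the array medians as deposited were 0.48 and -0.27, so the plant spots lay closer together as deposited. At 16 h the plant medians differed by 0.36 in Leghorn, 0.96 in Fayoumi and 0.78 in broiler, between the bounds of 0.2 and 1 taken over from the test at 2 h, and both broiler medians were below 0. The test did not decide there, and a response and a bias cannot be told apart at 16 h by these spots. A bias of dye or brightness may be the cause, since the plant median followed the first component of the chicken probes (r = 0.94 over 23 arrays). That relation does not show whether the dyes were exchanged between the arrays of a group. At 16 h the plant medians had 1 sign on both arrays in Leghorn (0.56 and 0.21) and broiler (-0.05 and -0.83). They had opposite signs in Fayoumi (0.50 and -0.46), as in each line at 2 h. With the replicate arrays turned, the plant spots had a mean of -1.10 ± 0.69 (SD, n = 6) in spleen at 2 h, so 3354 of the 3769 probes called there, the negative ones, went the same way as spots that are not named for chicken genes, and the 415 positive ones went the other way. A response that differed between birds, in addition to such a bias, stays open and untested.

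The 499 positive probes of Fayoumi cecum at 16 h leaned to 1 side of the difference between the spleen arrays of a group at 2 h. This difference is called the bias trend here, although its cause was not settled. Their median difference between the spleen arrays, averaged over lines and halved, was -0.46 against -0.01 for all probes, and the lowest median of 10000 random lists was -0.14. Over all probes the mean of this group correlated at -0.58 with the same difference, so probes chosen for a high mean would lie on this side. The random lists treated probes as independent and did not keep the shares of the clone groups, so they add little to this correlation. Of the 499, 367 remained called once the bias trend of the spleen arrays was removed, but only 5 with the SE from before the correction. Their median log2 ratio was 1.97 before (median SE 0.45) and 1.22 after (median SE 0.29), so the calls stayed because the spread fell with the ratios. After the same step 100 of the 552 probes called were negative, against 1 of 500 before. The medians of all DT40subNB and all Pat clones went from 0.47 to 0.04 and from 0.43 to -0.09. The removal centres the ratios along the trend whatever gave rise to them, so these shifts do not tell the cause. The 499 probes highest on 1 of the 2 arrays had medians of 0.87 and 0.90 on the other after the removal, and 1.75 and 1.74 before it. In the other 10 pairs of arrays the medians after the removal ran from -0.29 to 0.32. The removal was not complete, since spleen pairs still correlated down to -0.18 after it. The test did not decide, and what remained of the trend cannot be told apart from another cause. A bias of the 2 cecum arrays with another shape and a challenge response of the Fayoumi line also stay open, and neither was tested.

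In cecum at 2 h, 4 differences between lines were flagged, among 60 pairs looked at. In these, both Leghorn arrays lay on 1 side of 0 and both arrays of the other line on the opposite side. Pairs with broiler cecum at 16 h, which had 1 array, could not meet this rule. Independent signs would flag at least as many, and the differences themselves were not tested. The 4 are not separate, since C00041 holds 73.3% of the probes and each array was centred on the median of all tested probes. The median of the C00041 clones was lower in Leghorn than in Fayoumi by a log2 difference of -0.17 and than in broiler by -0.19. That of the DT40subNB clones was higher by 0.46 and 0.54. With the bias trend removed these differences were -0.07, -0.08, 0.13 and 0.17. As deposited, the C00041 medians were -0.10, 0.25 and 0.59 in Leghorn, Fayoumi and broiler, and the DT40subNB medians 0.25, -0.02 and 0.21, so the broiler sign of DT40subNB flipped. With the replicate arrays turned, the Leghorn medians flipped to 0.07 and -0.16, and the broiler medians to -0.01 and 0.01.

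The opposition of Leghorn to the other lines in cecum at 2 h was also seen over all probes, with correlations of -0.37 and -0.39. The plant medians were -0.36 and -0.26 on the Leghorn arrays and between 0.23 and 0.55 on the others, as arrays of different orientation would have. With the bias trend removed, the lower of the 2 correlations was -0.19, between the bound of -0.1 set for a bias and that of -0.25 set for a line difference. The test, whose bounds were set before its result was seen, did not decide, and bias and line cannot be told apart for these arrays, since by the plant spots both arrays of a line lie on 1 side. Without the Leghorn replicate array the correlations were -0.08 and -0.05.

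Other sign patterns of the arrays, or other splits within lines, were counted for the comparisons over all lines. The real count was 0 in each of the 8, so every pattern or split gives at least as many whatever the data, and these counts say nothing about chance. They were 32 of 32 for spleen at 2 h, spleen at 16 h and cecum at 2 h, 16 of 16 for cecum at 16 h, where the patterns are also too few for a share under 0.05, and 100 of 100 splits for each difference between times or tissues. The highest other counts were 4075 for spleen at 2 h, 0 for spleen at 16 h, 2 for cecum at 2 h, 424 for cecum at 16 h, 6261 and 150 between times in spleen and cecum, and 0 and 1 between tissues at 2 h and 16 h. The pattern with 4075 set the 3 arrays with plant medians above 0 against the 3 below. These are the replicate arrays and the first arrays. It thus repeats the setting with the replicate arrays turned, where those of the other groups were turned as well and 3769 probes passed. It is not separate support for a bias. In the spleen split with 6261, plant medians were above 0 on 1 of 6 arrays in 1 part and on 5 of 6 in the other, and in the cecum split with 150 on 5 of 6 and 0 of 5.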

How the results depend on the processing

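The 24 counts were recomputed under 14 other settings and without each of the 23 arrays, except that 16 counts (single lines and line differences) were not run with averaged arrays and the 2 tissue differences not with each tissue fitted alone. Of the values under the settings, 229 lay within 1.5 times the original count and 89 did not; the cause was not tested unless stated. Both filters on missing values changed nothing, since no tested probe lacked a value. The alternatives for gene lists could not be run, nor could those that need intensities.

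With the values as deposited, the counts were 2 for Fayoumi cecum at 16 h, 3 for Leghorn cecum at 16 h (1 positive, 2 negative), 3 for Leghorn spleen at 16 h, 13 for broiler spleen at 16 h, all negative, and 1 each for broiler cecum and broiler spleen at 2 h. They were 4 and 2 for the mean responses of spleen at 2 h and 16 h, 4, 2 and 1 for the line differences of spleen at 2 h, spleen at 16 h and cecum at 16 h, and 1 for each time difference. PEN_c-rel reversed to 0.53 in spleen at 2 h and to -0.0538 at 16 h. Scaled between arrays, the counts were 864 for Fayoumi cecum at 16 h, 1 for Fayoumi cecum at 2 h, 0 for Leghorn cecum at 16 h and Leghorn spleen at 2 h, 7 for Leghorn spleen at 16 h and 13 for broiler cecum at 16 h. The mean responses had 3 in cecum and 5 in spleen at 16 h.

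Array weights gave 1939 for Fayoumi cecum at 16 h, 3 at 2 h, 0 for Leghorn cecum at 16 h and Leghorn spleen at 2 h, 5 for Leghorn spleen at 16 h, 1 for broiler cecum at 16 h, and 1 and 4 for the mean responses of cecum at 2 h and spleen at 16 h. With each tissue fitted alone, Leghorn cecum at 16 h had 0 and Leghorn spleen at 2 h had 6. Averaged replicate arrays gave 130 for the mean response of cecum at 16 h, all positive. The slide number range as a random block gave 772 for Fayoumi and 6 for Leghorn cecum at 16 h, and 11, 4 and 2 for the mean responses of cecum at 16 h, spleen at 16 h and spleen at 2 h.

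With the planned replicate block within each tissue, the counts were 312 for Fayoumi cecum at 16 h, 0 for Leghorn cecum at 16 h, 1 for the mean response of cecum at 16 h and 1 for the line difference of spleen at 2 h, and no other count moved by over 1.5 times (Leghorn spleen at 2 h had 31, all positive). With the replicate block within each tissue and time, chosen after seeing the data, they were 2378 for Fayoumi, 349 for Leghorn and 25 for broiler cecum at 16 h, and 555 and 14 for Leghorn spleen at 2 h and 16 h. The mean responses had 880 in cecum at 16 h, 223 in spleen at 2 h and 4 in spleen at 16 h, the line differences 548 in cecum at 16 h and 28 in spleen at 2 h, and the time difference of cecum 261. The means themselves are the same with this block, and only the estimated spread differs.

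With the sign of the replicate arrays turned, Fayoumi and Leghorn cecum at 16 h had 0, broiler cecum at 16 h 1, Leghorn spleen at 2 h 1795, broiler spleen at 2 h 504, the mean response of spleen at 2 h 3769, the time difference of spleen 4757 and the tissue difference at 2 h 1832. PEN_c-rel in cecum at 2 h reversed to -0.13, and the correlation of the Leghorn and Fayoumi means to 0.20.

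Among the other settings chosen after seeing the data, the control-spot covariate gave 1700 for Fayoumi cecum at 16 h, 1 at 2 h, 141 for Leghorn cecum at 16 h, 6 and 107 for Leghorn spleen at 16 h and 2 h, 13 for broiler cecum at 16 h, 315, 5 and 6 for the mean responses of cecum at 16 h, spleen at 16 h and spleen at 2 h, and 463 and 25 for the line differences of cecum at 16 h and spleen at 2 h. All 499 positive probes of Fayoumi cecum remained called with it. With the bias trend removed, the counts were 552 for Fayoumi cecum at 16 h (452 positive, 100 negative), 118 for Leghorn cecum at 16 h, 6 and 139 for Leghorn spleen at 16 h and 2 h, 26 for broiler cecum at 16 h, 75, 4 and 7 for the same mean responses, and 85 and 17 for the same line differences. Without the 3 widest arrays they were 1722 for Fayoumi and 0 for Leghorn cecum at 16 h, 5 and 19 for Leghorn spleen at 16 h and 2 h, 1 for broiler cecum at 16 h, 8 for broiler spleen at 2 h, 3 and 1 for the mean responses of spleen at 16 h and 2 h, and 581 and 16 for the line differences of cecum at 16 h and spleen at 2 h.

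Without single arrays, a group's remaining array is assumed to vary like the other groups. The counts ran from 0 to 1078 for Fayoumi cecum at 16 h, 0 to 699 for Leghorn cecum at 16 h, 8 to 688 for Leghorn spleen at 2 h, 0 to 18 for Leghorn spleen at 16 h, 0 to 36 for broiler spleen at 2 h, and 0 to 1 for broiler cecum at 2 h and at 16 h. For the mean responses they ran from 0 to 743 in cecum at 16 h, 0 to 1 in cecum at 2 h, 0 to 3 in spleen at 16 h and 0 to 4 in spleen at 2 h. For the line differences they ran from 0 to 45 in cecum at 16 h, 0 to 1 in cecum at 2 h and 0 to 10 in spleen at 2 h, for the time difference of cecum from 0 to 16 and for the tissue difference at 16 h from 0 to 22. PEN_c-rel ran from -0.26 to 0.0741 in spleen at 2 h and from -0.0536 to 0.30 at 16 h. The remaining counts stayed at 0 without any single array. No signal over background was at hand, so dim probes could not be set apart.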

Other observations

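DT40subNB clones were over-represented among the positive probes of Fayoumi cecum at 16 h under 3 settings chosen after the result was seen, and under some planned ones. With the bias trend removed they were 141 of 452 positive probes, an odds ratio of 3.69 against 4.93 without it (Fisher's exact test, adjusted p = 3.14e-29). With the control-spot covariate there were 479 (odds ratio 3.76), and without the 3 widest arrays 480 (odds ratio 3.70). Of the planned settings, scaled arrays gave 294 (odds ratio 4.55), array weights 529 (3.68) and the replicate block within each tissue 121 (5.14). As deposited only 2 were called, and with the sign of the replicate arrays turned 0. Pat clones among the positive probes of Leghorn spleen at 2 h went from 15 to 42 with the bias trend removed (adjusted exact p = 2.86e-10), and to 0 with scaled arrays. The excess of Pat clones did not hold without the first Leghorn array, where they were 14 of 550 positive probes (odds ratio 0.17).

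The spots named for chicken genomic DNA lay far from the array median on 2 arrays, at 1.56 on the first Leghorn spleen array at 2 h and at -1.46 on the Leghorn spleen replicate array at 16 h. Spreads also differed: the median absolute deviation ran from 0.245 to 1.20 over the 23 arrays, and the 3 above 0.9 were the replicate arrays of Leghorn spleen at 2 h, broiler spleen at 2 h and Leghorn cecum at 16 h.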
